A study of Mus musculus with 2 samples.

How the data were processed

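Poly(A)-containing RNA was measured in 2 libraries, 1 from DMSO-treated and 1 from J007-treated mouse myeloma cells of a line from an IL6 and Myc transgenic mouse. Total RNA was purified on Qiagen RNeasy columns and libraries were made with a stranded KAPA mRNA kit, per the labels' protocols. Partek, DESeq2 and the mouse genome build mm10 are named per the submitters' processing notes, with no versions or roles. The aligner, the annotation version, whether counting used strand, and the dose and time of J007 are not given in the sources used here. Nothing in the labels says how the cultures were kept apart.

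The deposited gene table holds estimated counts for 55291 genes, and 18.0% of the DMSO values and 18.5% of the J007 values are not whole numbers within 1e-06, so the authors' counting shared some reads between genes. One column name spells J007 with letters in place of zeros and was matched by the rest of the sample title. The authors' deposited comparison table gives a p-value and an adjusted p-value per gene, a ratio of J007 over DMSO, its log2, a signed fold change and a CPM value per library. Per the values, the authors' deposited CPM was the estimated count divided by a library total larger than the sum of the gene table, of which 78.1% and 80.3% lay in the gene table. The model behind the authors' deposited p-values with 1 library per treatment is not given in the sources used here. Counts were assumed whole when the design was set, and the estimated counts were rounded to whole numbers first.

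Groups, gene lists, the rule for named genes and the other settings to be tried were set before the data were examined. Size factors came from TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.03 for DMSO and 0.973 for J007 on totals of 24212933 and 29429105 counts. The log2 ratio of J007 over DMSO CPM was given an exact (Clopper-Pearson, conditional binomial) 95% interval, which treats reads as independent molecules and covers counting error only. A gene was counted where its mean was at least 5 CPM, its ratio at least 2-fold and its interval excluded equality. The floor of 3 counts was 0.124 CPM for DMSO and 0.102 CPM for J007. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used.

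The genes named were the 12 highest and 12 lowest with a mean of at least 10 CPM, leaving out predicted symbols, identifiers, ribosomal pseudogenes and immunoglobulin segments. Added to these were Hnrnpa1, Myc, Ccnd1, Xiap, Irf4, Xbp1, Hspa5, Ddit3 and Cdkn1a, and up to 4 members of each list with the largest absolute log2 ratio; 1 such list member is not reported here. Of 34 gene lists, 28 had at least 5 measured members, and 24 pairs of lists shared genes. A list's median was placed among the medians of 10000 random lists of the same size matched on mean CPM in 20 bins. No p-value was computed across genes.

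Transcript GC content and length came from the longest transcript per gene in GENCODE M21 for mm10, available for 99.4% of measured genes. Of 53186 symbols also in that annotation, 99.3% had the same chromosome, start and end once the deposited end was lowered by 1 base, and ends are printed that way. A quadratic trend of the log2 ratio with GC content and log length was fitted on 9025 nuclear protein-coding genes and removed as an alternative chosen after the data were seen. Other alternatives were DESeq2 1.42.0 size factors, library totals, upper quartile scaling, no filter, a mean of at least 20 CPM, a pseudocount of 1 CPM, a fold of 1.5, an interval wholly past 2-fold and 50 expression bins. Counting restricted to nuclear protein-coding genes, random lists drawn from them, and signs compared with the authors' deposited table once the median difference was taken out were also chosen after the data were seen.

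The steps were tested on simulated data. In counts drawn for the 10192 genes of the J007 against DMSO comparison, 96.0% of genes set to 2.5-fold and 100.0% of those set to 4-fold were called. Of unchanged genes 0.0% were called, and 95.2% of their intervals covered the true ratio. These counts were drawn with counting error only, which the intervals assume, so the shares check the code and not spread between cultures. Of 100 lists picked at random from shuffled ratios, 4.0% fell outside the central 95%. That share too follows from the draw. Of 20 lists shifted by 0.2, 100.0% lay at or over percentile 97.5. That shift is larger than most list medians given below, so this share does not show that smaller shifts would be found. A GC slope of 2 put into the ratios was recovered as 2.04.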

Results

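RNA was sequenced from a cultured mouse myeloma line, a plasma cell tumour line derived from an IL6 and Myc transgenic mouse. One library came from cells given the solvent DMSO and 1 from cells given J007, a compound the labels describe as an inhibitor of hnRNP A1, an RNA-binding protein that acts in splicing and translation. The gene table held 24212933 estimated read counts for the DMSO library and 29429105 for the J007 library. The comparison addressed how the transcriptome differed after J007. With 1 library per treatment there was no replicate check and no test was possible, so every difference given is between these 2 libraries, not between the treatments. Bracketed ranges are exact 95% intervals that cover counting error only.

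Most genes lay close to equality in the 2 libraries. Among 10192 genes with a mean of at least 5 CPM, the count scaled to library size, the quartiles of the log2 ratio of J007 over DMSO were -0.12 and 0.13, and 98.7% lay within 1.5-fold. At least 2-fold differences were seen for 13 genes higher and 18 genes lower in the J007 library. The 13 higher genes comprised 3 mitochondrially encoded mRNAs, 5 pseudogenes, the noncoding RNA Bc1 and 4 nuclear protein-coding genes. The 18 lower genes included 7 of the rRNA, misc_RNA, ribozyme or miRNA biotypes, 4 pseudogenes and 4 protein-coding genes. At 1.5-fold the numbers were 101 higher and 31 lower. Not all genes past 2-fold are separate signals, since mt-Co3 and Gm28437, and mt-Atp6 and Gm10925, had nearly the same counts. Rn7s1 and Rn7s2 had identical counts, as did Gm12895 and Gm12896.

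**Figure D1:**
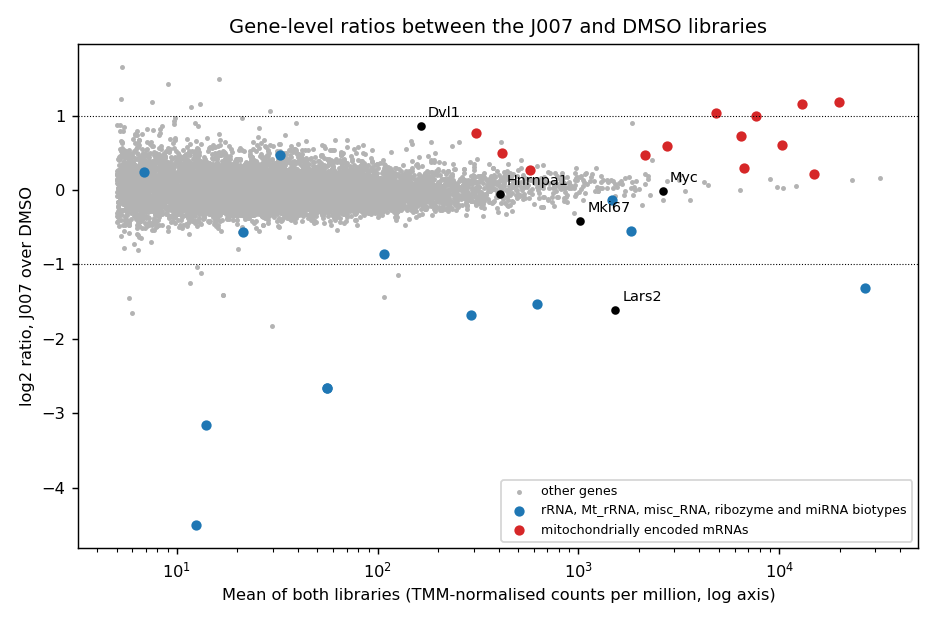
Each point is 1 of 10192 genes, with its mean level in both libraries on the x axis (TMM-normalised CPM, log axis) and its log2 ratio of J007 over DMSO on the y axis; dotted lines mark 2-fold. Mitochondrially encoded mRNAs (red) lie above 0, and most structural RNA biotypes (blue) and Lars2 lie below it, while Myc (-0.02) and Hnrnpa1 (-0.05) lie near 0.

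Hnrnpa1, which encodes the protein J007 is labelled to inhibit, was at nearly the same level in both libraries. Hnrnpa1 (chromosome 15, 103240432 to 103246692, mm10) had 412 CPM in the DMSO library and 398 CPM in the J007 library, a log2 ratio of -0.05 (-0.09 to -0.01). Myc, counted at its mouse locus (chromosome 15, 61985391 to 61990374), had 2646 and 2615 CPM, a log2 ratio of -0.02 (-0.03 to -0.00). Scaled by library totals these ratios were -0.13 and -0.095, and once a trend with GC content and length was removed they were 0.00 and -0.11. Myc ranked 10th by mean level among nuclear protein-coding genes. Counts per gene do not tell whether reads of the Myc transgene are among its counts. An inhibitor of a protein need not alter its mRNA, so the Hnrnpa1 level does not check the labels. Counts per gene show neither splicing nor translation, the processes in which hnRNP A1 acts.

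The mRNAs of the hnRNP family, which bind nascent transcripts and guide their processing, were mostly lower in the J007 library. The median log2 ratio of 28 family members was -0.14, with 20 intervals below equality and 1 above, and no member differed by 1.5-fold. Hnrnpr had a log2 ratio of -0.33 (-0.43 to -0.23), Syncrip -0.32 (-0.38 to -0.26), Ptbp3 -0.32 (-0.40 to -0.24) and Hnrnph2 -0.25 (-0.34 to -0.17). Once a trend with GC content and length was removed, these were -0.01, -0.08, -0.14 and -0.15, and the family median was -0.10. The SR proteins and their kinases, which act beside hnRNPs in splice site choice, had a median of 0.09 over 18 members, with 11 intervals above equality and 3 below. That median was 0.01 when scaled by library totals and 0.16 with the trend removed. Clk3 had a log2 ratio of 0.46 (0.40 to 0.52), Clk2 0.29 (0.20 to 0.38), Srsf7 0.25 (0.18 to 0.31) and Srpk1 0.23 (0.14 to 0.31). The central 95% of 10000 random lists matched on expression spanned -0.07 to 0.08 for the hnRNP family and -0.10 to 0.08 for the SR list.

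Genes with internal ribosome entry sites tied to hnRNP A1 did not move together. The 8 measured members had a median of 0.03, inside the random range of -0.13 to 0.14. Xiap, an inhibitor of caspases, had a log2 ratio of -0.42 (-0.56 to -0.28) and Sirt1 -0.32 (-0.51 to -0.13), while Vegfa had 0.26 (0.20 to 0.33) and Srebf1 0.22 (0.13 to 0.31). Xiap was at -0.21, Srebf1 at 0.08 and the list median at -0.03 with the GC and length trend removed. Ccnd1 had 2 counts in each library, at or under the floor of 3 counts, so no ratio is given. Its relative Ccnd2 was the abundant D-type cyclin, with 1103 CPM in the DMSO library and 1002 CPM in the J007 library. The 43 measured Myc-activated targets, many of them acting in ribosome assembly, had a median of 0.00, with Ppan at 0.28 (0.23 to 0.33), Rabepk at -0.30 (-0.51 to -0.10), Tfb2m at -0.27 (-0.36 to -0.17) and Ppat at -0.25 (-0.30 to -0.20).

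Proliferation genes were lower in the J007 library. Of 40 G2 and mitosis genes, 29 had intervals below equality and 0 above, with a median log2 ratio of -0.16 against a random range of -0.07 to 0.05. Mki67, a marker of cycling cells, went from 1167 CPM in the DMSO library to 875 CPM in the J007 library, a log2 ratio of -0.42 (-0.44 to -0.39). Cenpf at the kinetochore had -0.40 (-0.50 to -0.30), the spindle assembly factor Tpx2 -0.37 (-0.44 to -0.29) and Cks2 -0.36 (-0.51 to -0.20). The 44 genes of S phase and DNA replication had a median of -0.08, with 19 intervals below equality and 3 above. Pola1 had -0.34 (-0.46 to -0.22), Cdc45 -0.29 (-0.42 to -0.16) and Exo1 -0.29 (-0.40 to -0.17), whereas Pold1 had 0.36 (0.27 to 0.46). Removing the GC and length trend put Mki67 at -0.29, Cenpf at -0.21, Pold1 at 0.17 and the S phase median at -0.12. No member of either list differed by 1.5-fold.

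All 13 mitochondrially encoded mRNAs, which specify subunits of the respiratory chain and of ATP synthase, were higher in the J007 library. Their share of all counts was 6.83% in the DMSO library and 11.03% in the J007 library, and their median log2 ratio was 0.60, with a range of 0.21 to 1.18. The log2 ratio was 1.18 (1.17 to 1.18) for mt-Nd1, 1.16 (1.15 to 1.17) for mt-Atp6, 1.03 (1.02 to 1.04) for mt-Co3 and 0.99 (0.983 to 1.002) for mt-Nd2. Counts of mt-Atp6, mt-Co2 and mt-Co3 lay within 5% of those of nuclear pseudogenes, so reads of these were shared in the table. The mitochondrial rRNAs were lower, with -0.14 (-0.16 to -0.12) for mt-Rnr1 and -0.55 (-0.56 to -0.53) for mt-Rnr2, which were -0.00 and -0.41 with the GC and length trend removed. The 50 nuclear-encoded oxidative phosphorylation genes had a median of 0.01, with Cox6c at 0.31 (0.22 to 0.39), Ndufb8 at 0.21 (0.13 to 0.28), Sdha at -0.19 (-0.25 to -0.12) and Cox7c at 0.18 (0.01 to 0.36).

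Several structural RNAs were lower in the J007 library, as were reads assigned to Lars2, which encodes mitochondrial leucyl-tRNA synthetase. The rRNA biotype took 3.93% of counts in the DMSO library and 1.49% in the J007 library, nearly all at the locus CT010467.1 (chromosome 17, 39846353 to 39848201), with a log2 ratio of -1.32 (-1.32 to -1.31). The log2 ratio was -4.51 (-5.09 to -3.98) for the ribosomal RNA gene n-R5-8s1 and -3.17 (-3.52 to -2.83) for Rmrp, the RNA of RNase MRP. It was -2.66 (-2.81 to -2.51) for Rn7s1 and Rn7s2, signal recognition particle RNA genes with identical counts, and -0.86 (-0.94 to -0.78) for Rn7sk. Lars2 (chromosome 9, 123366927 to 123462666) went from 2297 CPM in the DMSO library to 749 CPM in the J007 library, a log2 ratio of -1.62 (-1.64 to -1.59), and Mir6236 had -1.54 (-1.57 to -1.50). The mean of Lars2 was 1523 CPM, against at most 84.7 CPM for 15 other mitochondrial synthetase genes. Whether its reads stem from another RNA was not settled, so no change of the synthetase mRNA is read from them. Not all short noncoding RNAs were lower, since the scaRNA gene Gm23119 had 0.92 (0.65 to 1.19) and Scarna17 0.77 (0.27 to 1.28).

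**Figure D2:**
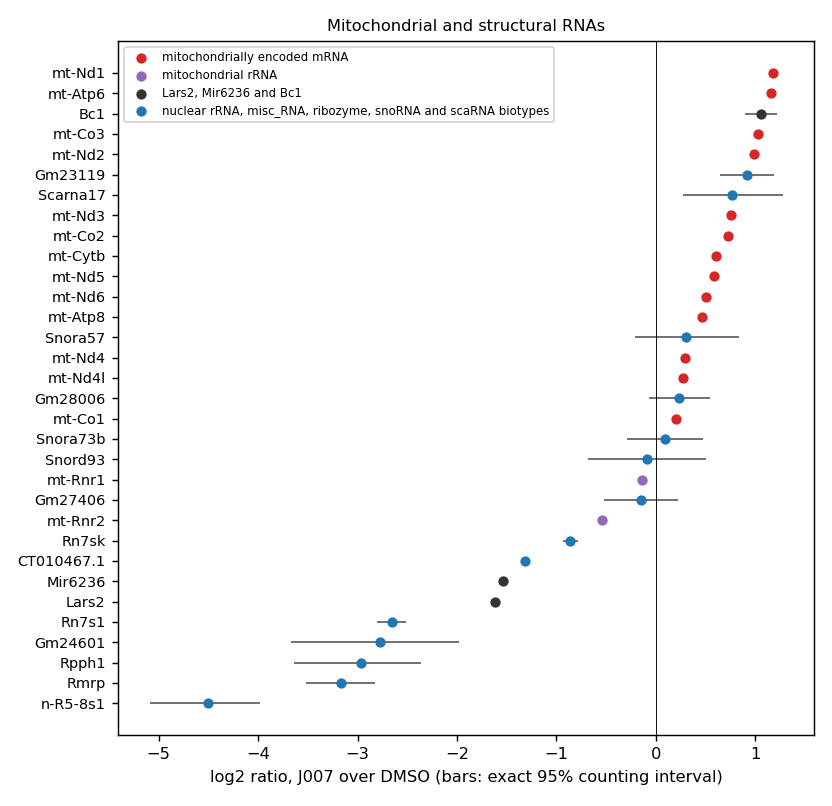
Log2 ratios of J007 over DMSO (x axis) with exact 95% counting intervals (bars) for mitochondrially encoded mRNAs, mitochondrial rRNAs, nuclear genes of short and structural RNA biotypes with at least 100 reads over both libraries, and Lars2, Mir6236 and Bc1. The mitochondrial mRNAs lie between 0.21 and 1.18, and the other RNAs spread from -4.51 for n-R5-8s1 to 1.06 for Bc1.

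Among other single genes, Dvl1, a Wnt pathway scaffold, was higher in the J007 library at 211 CPM against 116 CPM, a log2 ratio of 0.86 (0.80 to 0.93). The corepressor gene Tle2 had 0.90 (0.67 to 1.15), the noncoding RNA Bc1 1.06 (0.90 to 1.22), Erdr1 0.84 (0.674 to 1.001) and Snhg20 0.74 (0.60 to 0.88). Erdr1 was at 0.49 and Dvl1 at 0.72 once the GC and length trend was removed. At the low end, Usp46 had -0.59 (-0.83 to -0.36) and Gas2l3 -0.55 (-0.71 to -0.39). The zinc finger genes Zfp600 at -1.04 (-1.27 to -0.80), Zfp979 at -0.64 (-0.77 to -0.50) and Zfp988 at -0.56 (-0.76 to -0.36) are paralogs near each other on chromosome 4, so their split of reads is uncertain. The other nuclear protein-coding genes past 2-fold, named after their values were seen, were Gm49450 (1.15), Insl3 (1.22), Serpina1c (1.43) and Gm28539 (1.65) on the high side and Gm45062 (-1.83) and Gm10800 (-1.11) on the low side. With the GC and length trend removed, Insl3 (0.97), Gm10800 (-0.97) and Zfp600 (-0.87) were no longer past 2-fold.

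The medians of several signalling and stress lists were slightly higher in the J007 library, though many members went either way or spanned equality. The 12 measured NF-kB targets had a median log2 ratio of 0.19, with 6 intervals above equality and 2 below, and with Nfkb2 at 0.38 (0.25 to 0.51), Relb at 0.32 (0.14 to 0.50) and Icam1 at 0.31 (0.22 to 0.40), but Rel at -0.35 (-0.50 to -0.20). The 13 IL-6 and STAT3 targets had a median of 0.14, with 4 intervals above and 1 below. They were led by Cish at 0.36 (0.12 to 0.60), Junb at 0.31 (0.25 to 0.38), Pim3 at 0.25 (0.13 to 0.38) and Il6ra at 0.23 (-0.10 to 0.55). The mouse gene Il6 had 0 counts in both libraries, and whether reads of the IL6 transgene would be counted there is not known. The 29 p53 targets had a median of 0.12 but went both ways, with 11 intervals above and 6 below. Members were Bax at 0.37 (0.29 to 0.46), Sesn2 at 0.33 (0.27 to 0.39) and the cell cycle inhibitor Cdkn1a at 0.30 (0.26 to 0.35) against Rrm2b at -0.44 (-0.64 to -0.23) and Trp53inp1 at -0.31 (-0.34 to -0.29). The p53 and the IL-6 and STAT3 medians came back inside the random range once a trend with GC content and length was removed (0.02 and 0.05), while the NF-kB median went to 0.11 and stayed past it. Junb was then at 0.07, Pim3 at 0.03, Bax at 0.11, Sesn2 at 0.17, Cdkn1a at 0.19, Rrm2b at -0.30 and Trp53inp1 at -0.15. Nfkb2 was likewise at 0.22, Relb at 0.19, Icam1 at 0.19 and Rel at -0.205. At a mean of at least 20 CPM the p53 median was 0.06 and the IL-6 and STAT3 median 0.00, also inside. The 25 autophagy and lysosome genes had a median of 0.11, with 13 intervals above and 1 below, and with Neu1 at 0.38 (0.32 to 0.44), Mcoln1 at 0.35 (0.22 to 0.47) and Tfeb at 0.28 (0.04 to 0.51), the last at 0.03 with the trend removed.

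The ribosomal protein genes and a list of long noncoding RNAs were also mostly higher in the J007 library. Of 77 cytosolic ribosomal protein genes, 71 had intervals above equality and 0 below, with a median log2 ratio of 0.18. Rpl11 had 0.72 (0.56 to 0.88), Rpl10a 0.65 (0.59 to 0.70), Rps14 0.59 (0.54 to 0.65) and Rpl10 0.58 (0.49 to 0.67). How reads were split with their copies is uncertain, since the copy Rpl10-ps3 had 65294 counts in the DMSO library against 1580 for Rpl10, at a log2 ratio of 0.13 (0.11 to 0.14), and Rpl10-ps1 had 12009, at -0.33 (-0.36 to -0.29). The 7 measured long noncoding RNAs had a median of 0.21. Their list was named nuclear-retained RNAs, but retention was not measured and may not hold for each member, such as Gas5. Mir17hg was at 0.60 (0.47 to 0.73), Gas5 at 0.41 (0.37 to 0.44) and Neat1 at 0.40 (0.38 to 0.42) against Kcnq1ot1 at -0.33 (-0.56 to -0.10). With the GC and length trend removed, Neat1 was at 0.63 and Kcnq1ot1 at 0.32, though the Kcnq1ot1 transcript is longer than those of 99.99% of the genes fitted.

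The medians of plasma cell genes and secretory stress genes lay near 0, though single members differed. The plasma cell list had a median of 0.04 over 22 genes, with Irf4, a transcription factor myeloma cells need, at -0.01 (-0.03 to 0.01), Cd93 at 0.29 (0.20 to 0.38), Ly6c2 at 0.20 (0.10 to 0.31) and Mef2c at -0.20 (-0.26 to -0.13). The list of ER chaperones and other XBP1 and ATF6 targets had a median of 0.06 over 29 genes, with 18 intervals above equality and 4 below. With the trend removed its median was 0.07, which was past its random range. Among the members of that list were Xbp1 at 0.19 (0.17 to 0.20), Hspa5 at 0.14 (0.12 to 0.15), Derl3 at 0.26 (0.19 to 0.32), Sec24d at -0.24 (-0.34 to -0.15) and Selenos at 0.18 (0.08 to 0.28). The 36 integrated stress response genes had a median of 0.04, with Ddit3 at 0.26 (0.10 to 0.42), Nupr1 at 0.37 (0.08 to 0.66), Cebpb at 0.34 (0.27 to 0.42) and Slc3a2 at 0.29 (0.26 to 0.33). With the trend removed, that median was -0.05, Cebpb was at 0.01, Xbp1 at 0.095, Derl3 at 0.09 and Hspa5 at 0.18. The plasma cell median was then 0.02 and Mef2c was at -0.045. Scaled by library totals alone, which lowers every ratio by 0.08, these medians were -0.04, -0.02 and -0.04, so their direction was not fixed.

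The remaining lists with at least 5 measured members had medians inside their random ranges. These were the immediate early genes (0.11, with Jund at 0.33), the Bcl-2 family (0.08, with Bmf at 0.25 and Bbc3 at 0.25), LXR targets (0.03, with Apoe at 0.67) and mature B cell markers (0.01, with Cd74 at 0.27). They also included NRF2 targets (0.01, with Slc7a11 at -0.24), HIF1 targets (0.01, with Hk1 at -0.19), proteasome subunits (-0.00, with Psmd1 at -0.18) and interferon-stimulated genes (-0.01, with Gbp3 at -0.17). The last were histones (-0.02, with H4c9 at 0.17), sterol synthesis genes (-0.04, with Stard4 at -0.27) and heat shock genes (-0.07, with Chordc1 at -0.28). With the GC and length trend removed, the immediate early median was 0.02 and Jund 0.01, and the Bcl-2 median was -0.00 and Bbc3 -0.04. Apoe was then at 0.47, Cd74 at 0.12, Slc7a11 at -0.05, Hk1 at -0.295, H4c9 at 0.08 and Chordc1 at -0.08. Scaled by library totals, the positive medians among these, except that of the immediate early genes, were negative, as were those of the Myc targets, the ribosome entry site genes and the nuclear oxidative phosphorylation genes. Once that trend was removed, the medians of the Myc targets (-0.05), the nuclear oxidative phosphorylation genes (-0.06), HIF1 targets (-0.04) and mature B cell markers (-0.01) were also negative, and that of the histones was 0.01. Of 28 lists with at least 5 measured members, 3 lay at or under percentile 2.5 and 8 at or over percentile 97.5. Random lists hold unrelated genes and spread less than genes regulated together, so these percentiles describe the libraries and test nothing.

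**Figure D3:**
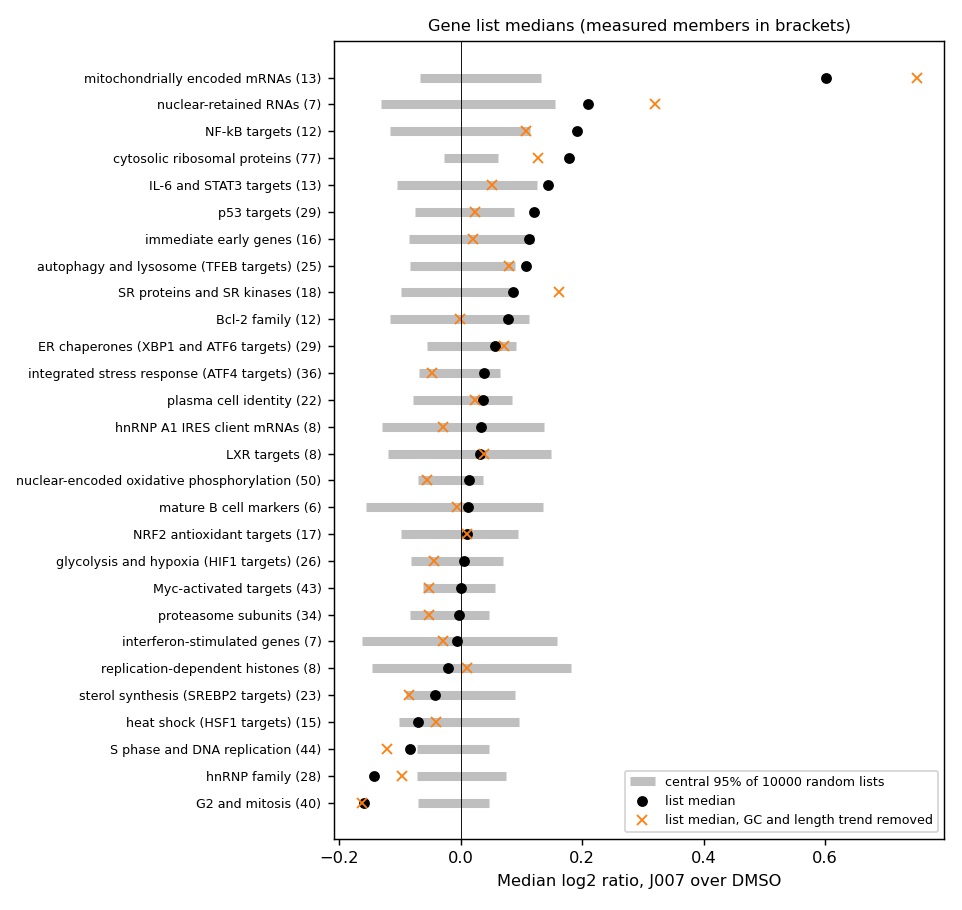
Median log2 ratio of J007 over DMSO (x axis) for 28 gene lists, with the number of measured members in brackets; grey bars span the central 95% of 10000 random lists matched on expression, and crosses give the median after a trend with GC content and length was removed. The mitochondrially encoded mRNAs stand highest at 0.60 and the G2 and mitosis genes lowest at -0.16.

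Markers of T and NK cells, stroma and granulocytes were scarce, whereas some macrophage and monocyte markers were not. T and NK cell markers summed to 155 counts in the DMSO library and 225 in the J007 library, stromal markers to 43 and 90, and granulocyte markers to 28 and 49, with no member of these lists at a mean of 5 CPM. Of the erythroid list only the transferrin receptor gene Tfrc, which dividing cells use, was measured, at -0.08 (-0.13 to -0.02). The macrophage and monocyte markers summed to 10281 and 12511 counts, of which Ctss alone had 7243 and 8459 (291 and 295 CPM). Of these 18 markers, 4 were measured and 6 had 0 counts in both libraries, so the sums rest on few genes and do not show that such cells were present. The 4 measured members had a median of 0.11, led by Cd68 at 0.27 (0.18 to 0.35). The 2 measured AHR targets were Nfe2l2 at -0.12 (-0.20 to -0.04) and Tiparp at -0.05 (-0.14 to 0.03). Tfrc was at 0.06 and Tiparp at 0.07 with the GC and length trend removed.

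The authors' deposited table listed 17885 genes, of which 40 had an adjusted p (FDR step up) under 0.05, 25 higher and 15 lower with J007. In the authors' deposited table, Mki67 had a log2 ratio of -0.45 with an FDR of 3.08e-07, and Lars2 had -1.66 with an FDR of 1.46e-125. Dvl1 had 0.82 with an FDR of 0.00623 and Trp53inp1 -0.35 with an FDR of 0.00166 in the authors' deposited table. Of the 40 genes, 12 were mitochondrially encoded and higher, 1 was mitochondrially encoded and lower, and 5 were pseudogenes of mitochondrial genes on chromosome 1, per the authors' deposited table. These p-values rest on 1 library per treatment and on the authors' model. Of 10187 genes in both tables, 91.6% had the same sign and Pearson's r across genes was 1.0, with a median difference of -0.04 in log2 ratio between the authors' deposited table and the values given here. With that difference taken out, 99.9% had the same sign. Both sets of ratios derive from the same counts with different library totals, so this likeness was built in and is no independent support.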

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

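The GC and length correction, the restriction to nuclear protein-coding genes and the removal of the offset from the authors' deposited table were chosen after the result was seen, and the other alternatives were planned. No paired analysis was possible because each treatment had 1 library and the values come from no test. The numbers of genes at least 2-fold higher and lower, 13 and 18, were 353 and 287 without a filter, where low counts enter, and 6 and 9 at a mean of at least 20 CPM, where fewer genes are counted. They were 101 and 31 at 1.5-fold and 4 and 4 among nuclear protein-coding genes. With the interval wholly past 2-fold, 8 genes were higher and 15 lower. Library totals gave 10 and 18, and the GC and length correction 14 and 15. Scaled by library totals, the log2 ratio was -0.13 for Hnrnpa1 and -0.095 for Myc, since that scaling lowers every ratio by the same amount. The share of genes with the sign of the authors' deposited table was 94.1% without a filter and 90.6% at 20 CPM. Taking the median difference out first gave 99.9%, so the difference in scale accounts for nearly all of the unlike signs. Under 3 other scalings and the pseudocount, 33 genes named singly gave 132 values, 0 of the other sign. The largest shift was 0.91, for n-R5-8s1 under the pseudocount. These signs could not change. A pseudocount keeps the sign of any ratio, and the scalings lower every ratio by at most 0.08. The smallest positive ratio among the 33 genes was 0.14, for Hspa5. With the GC and length correction 2 of the 33 changed sign, Hnrnpa1 to 0.001 and Irf4 to 0.025, while Myc went to -0.11, since that correction acts on each gene by its composition and length. The sign also changed for 6 of 113 list members, among them Kcnq1ot1, Bbc3, Tfrc and Tiparp. In every setting 3 list medians lay at or under percentile 2.5, and 6 to 9 at or over percentile 97.5. The 3 other scalings shift list medians and random medians alike, so they could hardly move a percentile and are no check of these numbers. The p53 and the IL-6 and STAT3 lists lost their place at 20 CPM and with the GC and length correction. The list of ER chaperones and other XBP1 and ATF6 targets passed percentile 97.5 with that correction. The immediate early genes passed it with random lists of nuclear protein-coding genes and the AHR targets without a filter.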

Other observations

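All tests of explanations here were chosen after the results were seen. Immunoglobulin transcripts, the main product of plasma cells, took 7.35% of counts in the DMSO library and 7.69% in the J007 library. The alpha heavy chain gene Igha had 33600 CPM in the J007 library against 30090 CPM, a log2 ratio of 0.16 (0.15 to 0.16), the kappa constant gene Igkc 0.14 (0.13 to 0.14) and the variable segment Igkv4-68 0.14 (0.13 to 0.15). The 3 genes thus kept nearly equal proportions to each other. With the GC and length trend removed, Igha was at 0.09, Igkc at 0.12 and Igkv4-68 at 0.14, so their order is not fixed. Ccnd2 had a log2 ratio of -0.14 (-0.16 to -0.11) and Ccnd3 0.09 (-0.05 to 0.24), which were -0.07 and -0.03 with the GC and length trend removed.

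Log2 ratios followed the base composition of transcripts. Across genes, which are not independent replicates, Pearson's r with GC content was 0.50 and Spearman's rho 0.52, and r with log length was -0.29. The median went from -0.16 in the decile of lowest GC content (39.4%) to 0.16 in the highest (59.1%), and GC content and length took 28.0% of the variance. After that trend was removed, Dvl1 (0.72), Rpl10a (0.60) and Rpl10 (0.59) stood highest among nuclear protein-coding genes with a mean of at least 50 CPM. Lars2 (-1.65), the spindle gene Aspm (-0.38), the mitotic kinase gene Plk1 (-0.37) and Raver1 (-0.36) stood lowest. The places of Rpl10a and Rpl10 depend on an uncertain split of reads with their copies. Rpl10a-ps1 had 20366 counts in the DMSO library against 4912 for Rpl10a, at a log2 ratio of 0.09.

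The mitochondrially encoded mRNAs were higher in the J007 library. Removing the GC and length trend left their median at 0.75, and the 10 mRNAs without a nuclear copy of like count had a median of 0.55, so neither the trend nor shared reads accounts for the whole. A smaller ribosomal RNA share would raise all other RNAs alike, but these mRNAs lay 0.61 above the nuclear protein-coding median. An equal rise of all of them is argued against by the gap of 0.97 between mt-Nd1 and mt-Co1, a test added once the one on mitochondrial rRNAs had decided nothing. More of every mitochondrial transcript after J007 cannot be told apart from RNA handling, because the higher of the mitochondrial rRNA ratios was -0.14 (-0.00 with the trend removed) and rRNA levels also depend on poly(A) selection; an effect of J007 stays open and untested.

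Ribosomal and other RNAs without poly(A) tails were lower in the J007 library, and a different carry-over of such RNAs past poly(A) selection is a candidate explanation whose outcome depended on which RNAs were counted. It was assessed under 3 definitions, each written after the values were seen, and the one of 9 genes was chosen when its outcome could already be foreseen. A hand-picked set of 7 RNAs, all lower, and 9 genes of the rRNA, misc_RNA and ribozyme biotypes, 7 of them lower, each had a median of -2.66, but 14 genes that also took in the snoRNA and scaRNA biotypes had a median of -0.50, quartiles of -2.74 and 0.20, and 2 genes higher, which decides nothing. Histone mRNAs, which for the most part also lack poly(A) tails, had a median of -0.03 over 14 genes. Whether their reads came from transcripts with or without tails is not known, so they do not decide whether carry-over acted on all such RNAs. Lars2, at a mean of 1523 CPM against at most 84.7 CPM for 15 other mitochondrial synthetase genes with a median log2 ratio of 0.13, moved apart from its family, and whether its reads stem from another RNA was not settled.

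The G2 and mitosis genes were lower in the J007 library. Their median was still -0.16 after the GC and length trend was removed, so that trend does not account for it. Over 2000 resamples of the members that median ranged from -0.19 to -0.12. This range covers spread among the members only, which are not independent replicates. Slower cycling after J007 and a difference between single cultures unrelated to J007, such as their density, cannot be told apart, because 1 library per treatment gives no spread between cultures. The ratios of nuclear protein-coding genes had an SD of 0.197 where counting alone would give 0.084, and this excess may hold either source or the library preparation.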
